A study of Arabidopsis thaliana with 8 samples.

How the data were processed

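Messenger RNA was sequenced from whole Arabidopsis seedlings grown for 10 days, in 4 groups of 2 libraries: wild type (WT), arid5, chr11/17 and rlt1/2. Per the labels, the plants are Col-0 grown on MS plates under 16 h of light at 23 °C and 8 h of dark at 21 °C. Nothing in the labels says that the libraries of a group come from separately grown plants, so p-values measure only the spread between these samples, which may be technical. Groups and replicate numbers were taken from the labels.

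Per the submitters' processing notes, HISAT2 and edgeR were used with the TAIR10 genome. Their versions, the read counter and the gene annotation are not given in the sources used here, nor is whether counting used strand. The authors deposited 3 tables, each with the WT libraries and the 2 libraries of 1 mutant, holding a normalised signal per gene: a non-negative value scaled to a common library size within that table. The tables were normalized separately, so levels are compared within a table only. They hold 23022 genes for arid5, 23427 for chr11/17 and 23248 for rlt1/2. Of these, 14, 16 and 15 entries carry a noncoding RNA identifier instead of a locus identifier; all other entries matched a locus of the TAIR10.1 reference table, which was used for gene names only. Of the gene names used in the lists below, some are older names that this table does not hold; their locus identifiers decide. No columns lacked a sample.

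The values are not whole numbers. They are reproduced by edgeR's quantile adjustment of whole read counts at a common library size, and that adjustment was inverted here: 100.0% of the values in each library came back as whole reads to within a relative tolerance of 1e-10, and the reads of each WT library were identical in all shared genes of the 3 tables, with 0 differences. On simulated tables the inversion returned 100.0% of the true reads. The recovered reads give totals, over the genes of all tables, of 25912666 and 25830687 for the WT libraries, 23135817 and 24227277 for arid5, 25411462 and 25205102 for chr11/17, and 27448388 and 29965298 for rlt1/2. Totals of the deposited values differ between the libraries of a table. PCR reads are not independent molecules, so every interval and floor given here covers counting error only.

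Before the data were examined, the comparisons, tests, alternatives, gene lists and the rule for naming genes were fixed. The design foresaw counts or normalized values; the deposited values being normalized, each mutant was compared with WT in its own table with limma's trend method (limma 3.58.1, R 4.3.3) on log2(value + 10), keeping genes with a value of at least 10 in at least 2 libraries. Fold changes on this scale understate the change of low genes. Genes nearly silent in WT are tested only where the mutant is high, which favours rises among the tested seed, floral identity and heat shock genes. P-values are two-sided and Benjamini-Hochberg adjusted over the genes of a table, with a threshold of 0.05. Adjusted p-values are from limma unless camera, edgeR or DESeq2 is named. Folds are ratios of group means of the recovered reads scaled by library size and edgeR's normalization factors; where a group had no reads the fold is a lower bound against 3 reads per library, and where it had 1 to 3 reads an exact 95% interval is given.

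The genes named follow the rule: the 5 mutated genes; FT, SOC1, FLC and the tested floral identity MADS-box genes; per mutant the 10 largest rises and the 10 largest falls among called genes with a higher group mean of at least 50 and no overlap between the groups' libraries; up to 4 called members of each list with the smallest adjusted p, or up to 2 where none was called; and the 5 genes per direction called in all 3 mutants with the largest smallest change. Names outside the rule are said to have been chosen after their values were seen. There were 20 gene lists with 340 members. The lists cover ISWI complex subunits, other chromatin remodellers, floral transition promoters, floral transition repressors, floral identity MADS-box genes, the circadian clock, meristem and leaf patterning, photosynthesis, flavonoid and anthocyanin synthesis, salicylic acid defence, jasmonate, cold and drought, heat shock, auxin, glucosinolate synthesis, iron deficiency and phosphate starvation, with seed, root and anther markers for other tissues. They were written from general knowledge of the genes. A list was tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists and mutants tested, where at least 3 members were tested. With an estimated correlation camera rests on the 2 residual degrees of freedom of a comparison, so few lists or families can pass it.

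Differences between mutants were tested on the recovered reads of all 8 libraries in 1 fit with edgeR 4.0.16 (quasi-likelihood, TMM), since WT reads are the same in every table. Because the 3 mutants share the WT libraries, overlaps and correlations are given beside 50 simulations of unchanged groups against those controls and beside the value for independent lists. The WT group has only 2 libraries and could not be split. Replicate libraries of a group were compared by chi-square over genes with at least 20 reads; the statistic per degree of freedom was 3.46 for WT, 5.51 for arid5, 14.89 for chr11/17 and 11.63 for rlt1/2, so no pair is 1 library deposited again.

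Alternatives were other pseudocounts and filters, median-of-ratios scaling and quantile normalization, limma without trend or with robust fitting, edgeR and DESeq2 1.42.0 on the recovered reads, a fold threshold, the replicate number as a block, and leaving out each library. Scaling to equal library totals, camera with a trend, and an overlap without the libraries labelled chr11/17 were added after seeing the data. A library left alone in its group was assumed to vary like the other group. The replicate statistic differed between groups, at 3.46 for WT against 11.63 for rlt1/2 and 14.89 for chr11/17. P-values and counts without 1 library may therefore be too small or too large.

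The procedure was tested on simulated counts with few changed genes. Of 20496 genes tested for arid5, 67 were changed 1.5-fold, 67 2-fold and 66 4-fold. Of the genes changed 2-fold, limma recovered 95.5% for arid5, 85.1% for chr11/17 and 85.1% for rlt1/2, and of those changed 1.5-fold 68.7%, 59.7% and 79.1%; 6.9%, 10.1% and 9.4% of its calls were false. The joint edgeR fit, simulated for chr11/17 against arid5, recovered 88.1% of 2-fold changes with 9.9% false calls. Each of these shares of false calls lies above the level set by the adjusted p threshold. In the data limma called 47.9% of genes for arid5, 71.8% for chr11/17 and 47.9% for rlt1/2. The simulated rates need not hold there, and scaling errors from widespread changes were not simulated. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for the inversion, and matplotlib 3.10.9 for the figures. Reads, read positions within genes and alignments were not used here.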

Results

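Transcript levels were measured by RNA sequencing in 8 libraries of 10-day-old Arabidopsis seedlings, 2 each from wild type (WT) and from plants labelled arid5, chr11/17 and rlt1/2. ARID5 is named in the study's title as a component of the ISWI chromatin remodelling complex; CHR11 and CHR17 are its ATPases, and RLT1 and RLT2 are DDT-domain partners of these ATPases. The series concerns the transition to flowering, and the comparisons ask which transcripts differ from WT when each part of the complex is mutated. Depth was 23135817 to 29965298 recovered reads per library in the genes of all tables. There were n = 2 libraries per group throughout. Log2 fold changes are mutant over WT on the log2(value + 10) scale, given with their standard error.

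The mutated genes were examined first. ARID5 (AT3G43240) fell by 1.95 ± 0.09 in arid5, from normalised read counts of 831 and 845 in WT to 213 and 206 (4.0-fold, adjusted p = 5.8e-08). RLT2 (AT5G44180) fell by 4.75 ± 0.14 in the libraries labelled rlt1/2, from 2292 and 2161 to 88 and 61 (30.2-fold, adjusted p = 1.92e-09). RLT1 (AT1G28420) was not called there (0.10 ± 0.09, adjusted p = 0.385; 1955 and 1970 in WT, 2318 and 1908 in the mutant). Without replicate 2 of the libraries labelled rlt1/2 its change was 0.24, and with equal library totals it was called higher (0.37, adjusted p = 0.00186). In the libraries labelled chr11/17, CHR11 (AT3G06400) rose by 1.28 ± 0.07, from 3077 and 2915 to 7226 and 7319 (2.43-fold, adjusted p = 8.03e-06), and CHR17 (AT5G18620) fell by 0.75 ± 0.08, from 1395 and 1316 to 771 and 834 (1.69-fold, adjusted p = 0.000123). The levels of CHR11 and RLT1 thus go against a loss of transcript. A mutation can leave transcript of the gene in place, and a total per gene does not show which part was read, so these libraries are called labelled chr11/17 and labelled rlt1/2, and every direction drawn from them rests on those labels.

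**Figure D1:**
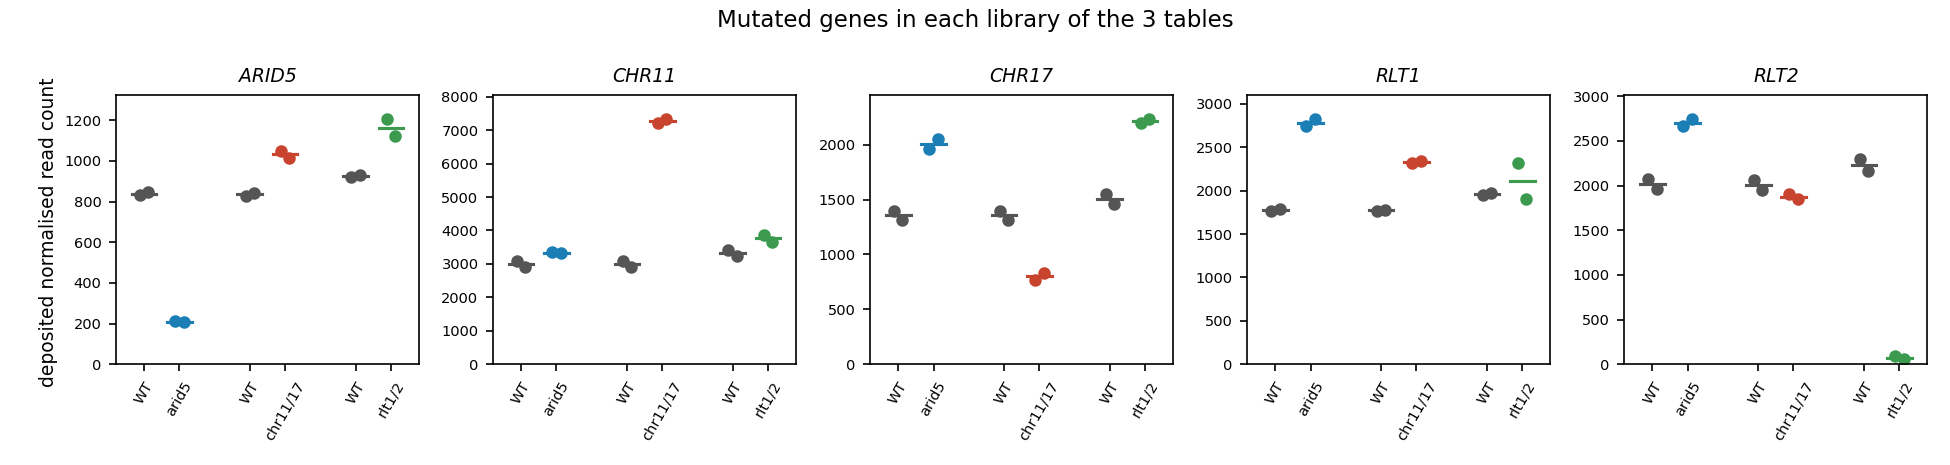
Deposited normalised read counts of the 5 mutated genes (vertical axes, linear from 0) in each library of the 3 tables; points are libraries and lines the means of 2. ARID5 lies at 213 and 206 in arid5, RLT2 at 88 and 61 in the libraries labelled rlt1/2, and CHR11 at 7226 and 7319 in those labelled chr11/17.

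Seedlings of arid5 carried higher transcript levels of AP3, SEP1, SEP3 and FT, and lower levels of FLC and SOC1. AP3 (AT3G54340), a petal and stamen identity gene, rose 32.1-fold from 8 and 5 to 238 and 200, SEP3 (AT1G24260) rose 13.6-fold from 153 and 189 to 2693 and 1976, and SEP1 rose 15.5-fold from 10 and 16 to 212 and 178. FT (AT1G65480), the mobile flowering signal made in leaves, rose 4.21-fold from 11 and 23 to 85 and 56, while SOC1 (AT2G45660), which promotes flowering, fell 2.18-fold from 1105 and 952 to 486 and 459. FLC (AT5G10140), a flowering repressor, had 15 and 20 reads in WT and no reads in either arid5 library, at least 6.4-fold lower. Transcripts of the 19 listed photosynthesis genes were also lower.

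Of 8 floral identity MADS-box genes tested in arid5, 3 rose, 1 fell and 4 were not called, and adjusted over the list alone the counts were 3 and 1. The changes were 3.77 ± 0.21 for AP3, 3.68 ± 0.13 for SEP3 and 3.19 ± 0.21 for SEP1, with adjusted p = 1.78e-07, 1.46e-08 and 4.79e-07. SEP4 fell by 0.48 ± 0.16 (adjusted p = 0.0278), a call lost without WT replicate 1 (adjusted p = 0.278) and under 3 other alternatives. FUL (-0.01), SHP1 (-0.01), AG (0.37) and PI (-0.19) were not called. As a set the list did not pass camera (adjusted p = 0.136), but passed it without WT replicate 1 (adjusted p = 0.0199), with DESeq2 (adjusted p = 0.0104) and with a filter at 50 (adjusted p = 0.0304), and not with an estimated correlation (adjusted p = 0.623). AP3 and SEP1 pass a filter at 50 only through arid5, so that filter favours a rise of the list. In limma with no filter on low values the floral identity list did not pass. Of 21 flowering repressors tested, 5 rose, 9 fell and 7 were not called, with 5 and 9 adjusted over the list alone (camera adjusted p = 0.348). MAF3, a relative of FLC, fell by 2.13 ± 0.14, SNZ by 1.77 ± 0.12, CDF1, which represses CO transcription, by 1.27 ± 0.08 and SVP by 0.82 ± 0.06; their adjusted p-values lay between 3.62e-07 and 1.15e-06. Of 13 promoters of flowering tested, 5 rose, 3 fell and 5 were not called, with 5 and 3 over the list alone (camera adjusted p = 0.717). FT rose by 1.61 ± 0.28 (adjusted p = 0.000536), AGL42 by 1.02 ± 0.23 (adjusted p = 0.00291; 0.64 without WT replicate 1), while the fall of SOC1 had adjusted p = 1.54e-06. Of 17 meristem and leaf patterning genes, 3 rose and 4 fell, as over the list alone (camera adjusted p = 0.844); YAB3 fell by 1.07 ± 0.09 and AS1 by 0.74 ± 0.07. Anther and seed markers were nearly silent in the same libraries: 1 of 11 anther markers was tested, LAP6, and was not called (-0.12), and of 2 seed genes tested CRA1, a seed storage protein gene, was called (8 and 2 in WT, 22 and 22 in arid5), a call lost without WT replicate 2 (adjusted p = 0.0662) and with DESeq2 (adjusted p = 0.055).

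**Figure D2:**
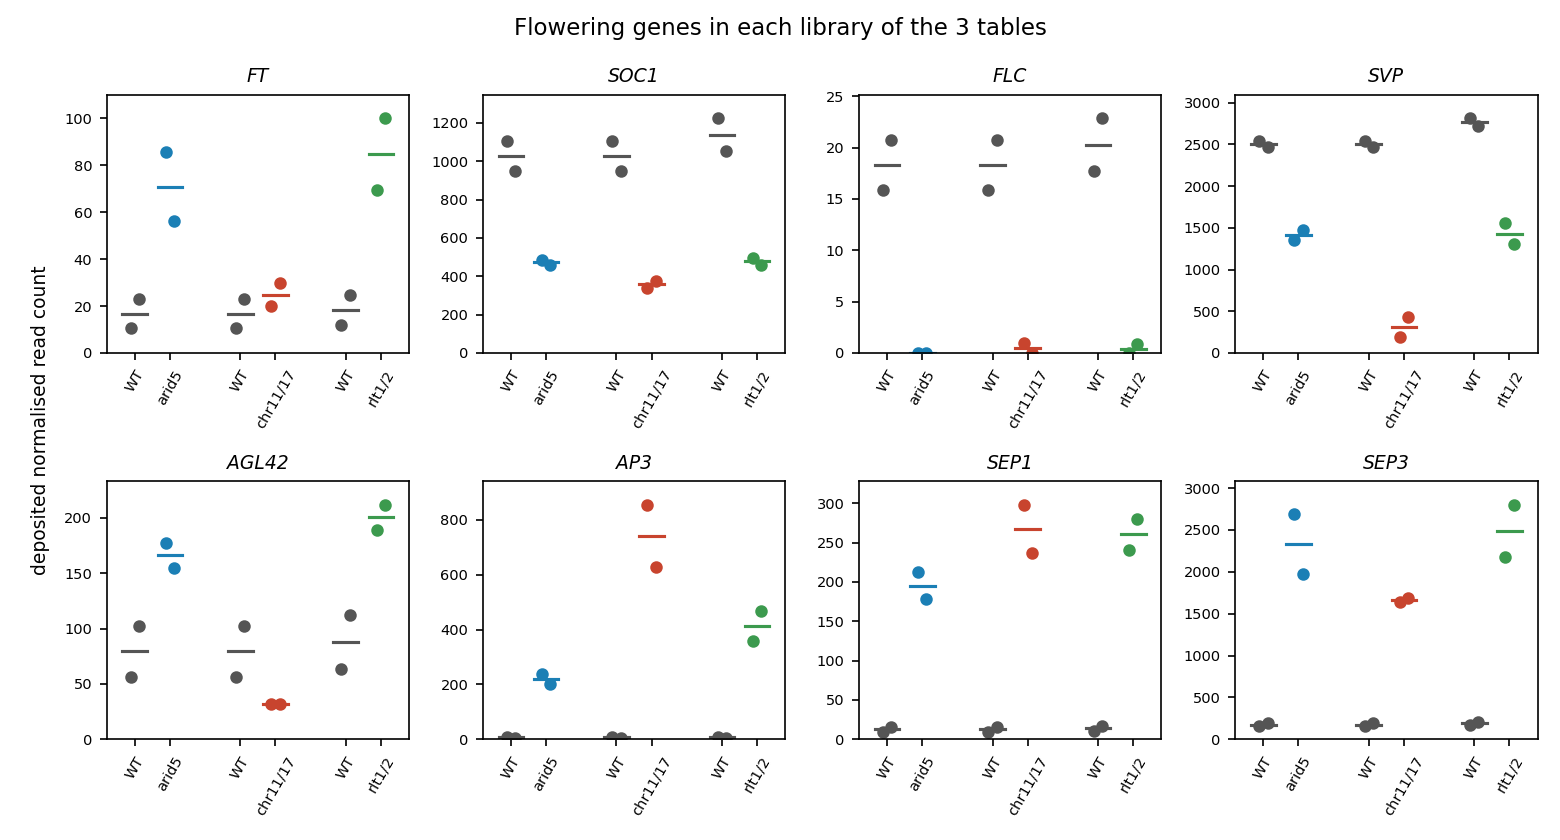
Deposited normalised read counts (vertical axes, linear from 0) of 8 flowering genes, SVP and AGL42 among them chosen after their values were seen, in each library of the 3 tables; points are libraries and lines the means of 2. AP3 lies at 8 and 5 in WT and at 238 and 200 in arid5, and FT at 11 and 23 in WT and at 85 and 56 in arid5.

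All 19 nuclear photosynthesis genes tested in arid5 fell, also adjusted over the list alone, with a median of -0.97 (camera adjusted p = 2.93e-09; adjusted p = 0.544 with an estimated correlation). LHCB1.2, a light-harvesting protein gene, fell by 1.63 ± 0.11 and RBCS2B, a Rubisco small subunit gene, by 1.18 ± 0.10, with adjusted p = 7.1e-07 and 2.14e-06. Several of these genes have near-identical copies, and counting that splits shared reads makes the value of each copy uncertain. With quantile normalization the set did not pass camera (adjusted p = 0.453): the median became 0 (SD 0.30, against 0.17), with 5 genes lower and 1 higher. That method gives each rank 1 value, and the median rank of these genes was 11 in WT and in arid5. PORA, an enzyme of chlorophyll synthesis, fell by 3.16 ± 0.17 on the log2 scale and RbcX1, a Rubisco assembly factor, 17.0-fold. Root markers moved in the same libraries: 9 of 17 rose and 1 fell, as over the list alone, with a median of 0.39 (camera adjusted p = 0.0112; adjusted p = 0.544 with an estimated correlation), a call lost with equal library totals (adjusted p = 0.0902) and with DESeq2 (adjusted p = 0.0581). NRT2.1, a nitrate transporter of roots, rose by 1.15 ± 0.13 and LRX1, a root hair gene, by 1.09 ± 0.12.

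Most of the listed flavonoid and anthocyanin genes rose in arid5, and most of the iron deficiency and the cold and drought genes fell. Of 14 flavonoid and anthocyanin genes 12 rose and 0 fell, as over the list alone, with a median of 0.70 (camera adjusted p = 0.000379; adjusted p = 0.544 with an estimated correlation). DFR rose by 1.43 ± 0.19 and LDOX by 1.25 ± 0.11, with adjusted p = 7.69e-05 and 2.72e-06. Of 17 iron deficiency genes 13 fell and 2 rose, as over the list alone, with a median of -1.16 (camera adjusted p = 0.0013; adjusted p = 0.544 with an estimated correlation). The iron-signalling peptide gene IMA3 fell by 2.91 ± 0.18, and bHLH100, a transcription factor gene of the iron response, went from 84 and 89 to no reads, at least 30.2-fold lower. F6'H1, which makes scopoletin, rose by 1.76 ± 0.07. Of 19 cold and drought genes 13 fell and 3 rose, as over the list alone, with a median of -1.08 (camera adjusted p = 0.000328; adjusted p = 0.544 with an estimated correlation). RAB18, a dehydrin gene, fell by 2.13 ± 0.13 and COR15A by 2.07 ± 0.13, with adjusted p = 3.4e-07 and 4e-07. Of 10 heat shock genes 3 rose and 0 fell, as over the list alone (camera adjusted p = 0.0405; adjusted p = 0.544 with an estimated correlation), a call lost without WT replicate 1 (adjusted p = 0.062) or WT replicate 2 (adjusted p = 0.058) and under 4 more alternatives besides the estimated correlation; HSP18.2 rose by 1.78 ± 0.20 and HSP90.1 by 1.11 ± 0.09.

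The other groups did not pass camera in arid5. Of 20 auxin response genes 5 rose and 10 fell, with 6 and 10 over the list alone (camera adjusted p = 0.158; 0.0108 without arid5 replicate 2, 0.00395 with equal library totals); the growth genes SAUR20 and SAUR21 fell by 1.41 ± 0.13 and 1.42 ± 0.11, and GH3.3, which conjugates auxin, rose by 1.63 ± 0.13. Of 18 clock genes 3 rose and 11 fell, with 4 and 11 over the list alone (camera adjusted p = 0.136), PRR7 falling by 0.99 ± 0.06. Of 17 jasmonate genes 8 rose and 5 fell, with 8 and 6 over the list alone (camera adjusted p = 0.276): CORI3 rose by 1.54 ± 0.09 and VSP2 fell by 1.42 ± 0.14. Of 18 salicylic acid defence genes 4 rose and 3 fell, as over the list alone; their median was -0.04 while their mean of 0.02 and the direction of camera (adjusted p = 0.717) were positive. FMO1 rose by 1.37 ± 0.18. Of 20 glucosinolate genes 9 rose and 2 fell, as over the list alone (camera adjusted p = 0.144, but past the threshold under 5 alternatives, with 0.0251 under quantile normalization), MYB29, a regulator of the pathway, falling by 0.67 ± 0.09. Of 12 phosphate starvation genes 6 rose and 1 fell, with 6 and 2 over the list alone (camera adjusted p = 0.228; 0.0257 without arid5 replicate 1), PPSPASE1 rising by 0.74 ± 0.12. Of 11 other chromatin remodellers 6 fell and 0 rose, as over the list alone (camera adjusted p = 0.0925), BRM falling by 0.50 ± 0.06. Of 9 ISWI subunits 5 rose and 2 fell, with 6 and 2 over the list alone; their median of 0.25 and the direction of camera (adjusted p = 0.369) were positive and their mean of -0.01 negative. RLT1 rose by 0.65 ± 0.06 and CHR17 by 0.56 ± 0.06.

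The changes in arid5 that led by size included BAM5, a beta-amylase (23.0-fold higher, from 206 and 265 to 6338 and 4540), GPT2, a plastid sugar phosphate transporter (16.6-fold), and TH8, a thioredoxin (21.5-fold). AT1G75945 had 0 and 1 reads in WT and normalised counts of 148 and 154 in arid5, a ratio of 289 (exact 95% interval 51.4 to 11400), and the noncoding AT3G05945 had 1 read in each WT library and reached 226 and 270, a ratio of 237 (65.3 to 1960). PCR1, a cadmium resistance gene, fell 188-fold (51.7 to 1560). In all, limma called 9846 of 20550 genes, 47.9%, with 4784 higher and 5062 lower; 885 and 612 of them changed more than 2-fold. Scaling to equal library totals moved the median of all genes from 0.003 to 0.252 and gave 9746 higher and 2680 lower, so directions of small changes are relative to the median gene. edgeR on the recovered reads called 9825 genes, 9722 of them called by both.

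In the libraries labelled chr11/17 AP3, SEP1 and SEP3 also rose, the 19 listed photosynthesis genes fell, and most listed jasmonate genes rose. AP3 rose 109-fold from 8 and 5 to 856 and 627, SEP2 38.0-fold from 7 and 9 to 335 and 300, and SEP3 9.73-fold from 153 and 189 to 1643 and 1687. SNZ, a repressor of flowering, fell by 3.16 on the log2 scale, while FT was not called (11 and 23 in WT, 20 and 30 in the mutant). LOX3, an enzyme of jasmonate synthesis, rose 84.5-fold from 250 and 247 to 22180 and 19840. LHCB2.2 fell 11.2-fold.

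Of 9 floral identity MADS-box genes tested in the libraries labelled chr11/17, 6 rose, 1 fell and 2 were not called, as over the list alone, with a median of 2.58 (camera adjusted p = 0.0539; 0.0172 without WT replicate 1). The list passed camera under 9 of 16 alternatives, edgeR (adjusted p = 0.0382) and DESeq2 (adjusted p = 0.0339) among them, and not with an estimated correlation (adjusted p = 0.544). AP3 rose by 5.47 ± 0.21, SEP2 by 4.16 ± 0.18, SEP1 by 3.63 ± 0.21 and SEP3 by 3.22 ± 0.11, with adjusted p between 1.71e-06 and 1.02e-05. STK, an ovule identity gene, rose 18.0-fold and SHP1 4.73-fold, SEP4 fell by 0.87 ± 0.20, and FUL (0.04) and PI (-0.30) were not called. Of 21 flowering repressors 7 rose and 11 fell, with 7 and 13 over the list alone (camera adjusted p = 0.38). SNZ fell by 3.16 ± 0.19 and TEM2 by 2.37 ± 0.12, SMZ rose by 2.27 ± 0.16 and ATC by 1.87 ± 0.09, and FLC had 1 read in these libraries, a ratio of 38.3 (exact 95% interval 6.44 to 1560). Of 13 promoters 3 rose and 7 fell, as over the list alone (camera adjusted p = 0.31); AGL14 fell by 2.12 ± 0.20, SPL9 by 1.51 ± 0.20 and SOC1 2.87-fold. FT had a change of 0.41 ± 0.29 (adjusted p = 0.239). Of 17 meristem and leaf patterning genes 6 rose and 7 fell, as over the list alone (camera adjusted p = 0.844): CUC1, an organ boundary gene, rose by 2.99 ± 0.19 and YAB3 fell by 2.95 ± 0.19. Of 18 listed seed genes 7 were tested in these libraries, and 6 rose and 1 fell, as over the list alone. Their median was 2.64 (camera adjusted p = 0.0543, and past the threshold under 3 alternatives, with 0.0251 without the filter on low values). The filter admits genes silent in WT only where the mutant is high, so the count of rises is partly fixed by it. CRA1 rose from 8 and 2 to 270 and 71, and SESA1, with 0 and 2 reads in WT, by a ratio of 78.1 (exact 95% interval 21.3 to 650). The anther marker LAP6 was called lower (-0.50, adjusted p = 0.013), a call lost without WT replicate 1 (adjusted p = 0.071) or WT replicate 2 (adjusted p = 0.0634), with DESeq2 (adjusted p = 0.0701) and with equal library totals (adjusted p = 0.054).

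All 19 photosynthesis genes fell in the libraries labelled chr11/17, also over the list alone, with a median of -2.56 (camera adjusted p = 2e-06; adjusted p = 0.619 with an estimated correlation). The 19 genes took 12.03% and 11.69% of the recovered reads in the WT libraries and 1.69% and 2.62% in these. RBCS2B fell by 3.17 ± 0.20 and LHCB2.2 11.2-fold, with adjusted p = 1.24e-05 and 1.83e-05. Root markers moved apart in the same libraries: 7 of 17 rose and 3 fell, as over the list alone, with a median of 0.08 (camera adjusted p = 0.717). WOX5, a root stem cell gene, rose by 1.77 ± 0.20 and SCR, a root patterning gene, fell by 0.61 ± 0.08.

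Of 19 jasmonate genes 17 rose and 0 fell in the libraries labelled chr11/17, with 18 higher over the list alone and a median of 3.17 (camera adjusted p = 1.33e-07; adjusted p = 0.544 with an estimated correlation). LOX3 rose by 6.34 ± 0.08, JAZ5, a repressor of jasmonate signalling, by 5.65 ± 0.13 and JAZ10 by 5.42 ± 0.09, with adjusted p between 1.18e-07 and 4.93e-07. Of 15 flavonoid and anthocyanin genes 13 rose and 1 fell, as over the list alone, with a median of 2.23 (camera adjusted p = 0.00065; adjusted p = 0.544 with an estimated correlation). PAP1, an activator of anthocyanin synthesis, rose by 5.12 ± 0.17 and DFR by 3.81 ± 0.25. Of 15 heat shock genes 12 rose and 0 fell, as over the list alone, with a median of 1.41 (camera adjusted p = 0.00251; adjusted p = 0.544 with an estimated correlation). HSP17.6A rose by 2.97 ± 0.19 and HSP90.1 by 2.23 ± 0.12. In arid5 only 10 heat shock genes were tested. The filter adds genes low in WT where the mutant is high, so the count of rises and the median partly follow from it. Of 17 iron deficiency genes 14 fell and 0 rose, as over the list alone, with a median of -1.71 (camera adjusted p = 0.000485; adjusted p = 0.544 with an estimated correlation). IMA3 fell by 4.07 ± 0.32. Of 11 other chromatin remodellers 9 fell and 0 rose, as over the list alone, with a median of -0.82 (camera adjusted p = 0.00288; adjusted p = 0.544 with an estimated correlation). CHR23 fell by 2.02 ± 0.14, CHR12 by 1.24 ± 0.08 and BRM by 1.07 ± 0.07, with adjusted p between 1.13e-05 and 2.1e-05.

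Most of the listed auxin genes fell in the libraries labelled chr11/17. Of 19 tested 12 fell and 2 rose, as over the list alone, with a median of -1.41 (camera adjusted p = 0.0112; adjusted p = 0.619 with an estimated correlation), and the call was lost without WT replicate 1 (adjusted p = 0.0632) or WT replicate 2 (adjusted p = 0.143) and with DESeq2 (adjusted p = 0.541). SAUR22 had no reads in these libraries and was at least 42.7-fold lower, while GH3.3 rose 78.6-fold and GH3.5 7.26-fold. SAUR19 to SAUR24 and the copies of light-harvesting genes are close relatives whose shared reads may be split by counting.

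The remaining groups did not pass camera in the libraries labelled chr11/17. Of 19 cold and drought genes 8 rose and 5 fell, as over the list alone; their median was -0.05 while their mean of 0.46 and the direction of camera (adjusted p = 0.569; 0.0385 with DESeq2) were positive. RD20 rose by 4.18 ± 0.17, ERD10 by 2.65 ± 0.08 and RD29A by 2.63 ± 0.10. Of 17 salicylic acid defence genes 7 rose and 7 fell, as over the list alone (camera adjusted p = 0.844): SAG13 rose 251-fold and WRKY70 fell by 1.89 ± 0.12. Of 20 glucosinolate genes 8 rose and 9 fell, as over the list alone (camera adjusted p = 0.858): CYP79B2 rose by 2.11 ± 0.07 and MYB29 fell by 2.06 ± 0.12. Of 12 phosphate starvation genes 3 rose and 7 fell, as over the list alone (camera adjusted p = 0.261), MGD3 falling 22.4-fold and PAP17 rising by 1.97 ± 0.12. Of 18 clock genes 5 rose and 9 fell, as over the list alone (camera adjusted p = 0.441): PRR5 rose by 2.72 ± 0.15 and PRR7 fell by 1.74 ± 0.07. Of 9 ISWI subunits 4 rose and 2 fell, as over the list alone (camera adjusted p = 0.716), PTM falling by 0.71 ± 0.07 and MSI3 rising by 0.81 ± 0.10. ARID5 was called higher (0.30 ± 0.07, adjusted p = 0.00716), a call lost without WT replicate 1 (adjusted p = 0.06), and RLT2 was not called (-0.10; -0.19 and adjusted p = 0.0378 with quantile normalization).

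Among the 10 largest rises by the naming rule in the libraries labelled chr11/17, DXPS1 and AT2G38240 had no reads in WT. DXPS1 reached 15220 and 13570 (at least 4580-fold), and AT2G38240 reached 2838 and 3202 (at least 962-fold). ELI3-2, an alcohol dehydrogenase gene, rose 2390-fold and GPT2 351-fold. Among the falls were EXPA8, an expansin (97.8-fold lower, from 4603 and 5207 to 38 and 62), ACD6 (197-fold) and FBA5, an aldolase (39.3-fold). limma called 14992 of 20878 genes, 71.8%, with 7485 higher and 7507 lower; 3420 and 3463 changed more than 2-fold. edgeR on the recovered reads called 14984, 14848 of them called by both. Equal library totals moved the median of all genes from -0.007 to 0.144 and gave 8828 higher and 6288 lower.

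In the libraries labelled rlt1/2, AP3, SEP1, SEP3 and FT rose and FLC and SOC1 fell, the directions seen in arid5. AP3 rose 55.3-fold from 9 and 6 to 360 and 467, SEP3 13.3-fold from 170 and 209 to 2181 and 2801, and SEP1 18.8-fold from 11 and 17 to 241 and 280. FT rose 4.6-fold from 12 and 25 to 69 and 100, and SOC1 fell 2.38-fold from 1223 and 1051 to 495 and 461. FLC had 1 read in these libraries, a ratio of 47.1 (exact 95% interval 7.91 to 1910).

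Of 10 floral identity MADS-box genes tested in the libraries labelled rlt1/2, 4 rose, 1 fell and 5 were not called, as over the list alone (camera adjusted p = 0.0653; 0.00471 without WT replicate 1). The list passed camera under 7 of 16 alternatives, edgeR (adjusted p = 0.0382) and DESeq2 (adjusted p = 4e-04) among them. It did not pass with an estimated correlation (adjusted p = 0.544). AP3 and SHP2 lay under 10 in WT and were tested only through the mutant, which favours rises. With no filter on low values the list passed camera (adjusted p = 0.0405). AP3 rose by 4.59 ± 0.21, SEP3 by 3.65 ± 0.13, SEP1 by 3.51 ± 0.21 and SHP2 by 1.45 ± 0.30 (0 and 3 reads in WT), with adjusted p between 4.37e-09 and 0.00157. SEP4 fell by 0.69 ± 0.18, a call lost without WT replicate 1 (adjusted p = 0.07), and FUL (-0.03), SEP2 (0.02), SHP1 (0.28), PI (-0.22) and AG (0.48) were not called. Of 21 flowering repressors 4 rose and 10 fell, with 5 and 10 over the list alone (camera adjusted p = 0.136): MAF3 fell by 2.45 ± 0.15, SNZ by 2.42 ± 0.13 and CDF1 by 1.24 ± 0.10, and ATC rose by 2.05 ± 0.12. With equal library totals this list passed camera (adjusted p = 0.0123). Of 13 promoters 6 rose and 2 fell, as over the list alone (camera adjusted p = 0.462). FT rose by 1.75 ± 0.27, AGL42 by 1.15 ± 0.22 and SPL4 by 0.92 ± 0.19, and SOC1 fell by 1.23 ± 0.10. Of 17 meristem and leaf patterning genes 1 rose and 7 fell, as over the list alone (camera adjusted p = 0.369), YAB3 falling by 1.19 ± 0.11. Of 18 listed seed genes 4 were tested, and 3 rose and 0 fell, as over the list alone, a count that the filter favours in the same way. The list passed camera (adjusted p = 0.0469, and 0.544 with an estimated correlation), a call lost without WT replicate 2 and under 8 other alternatives. CRA1 rose from 9 and 3 to 28 and 30. LAP6, the only anther marker tested of 11, had a change of -0.31 (adjusted p = 0.0827; 0.0247 with quantile normalization and 0.0374 without a trend).

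All 19 photosynthesis genes fell in the libraries labelled rlt1/2, also over the list alone, with a median of -1.12 (camera adjusted p = 4.93e-09; adjusted p = 0.557 with an estimated correlation). With quantile normalization the set did not pass (adjusted p = 0.302): the median became -0.03 (SD 0.26, against 0.15), with 5 genes lower and 0 higher, and the median rank of these genes was 11 in WT and in the mutant. LHCB1.2 fell by 1.57 ± 0.23 and RBCS2B by 1.29 ± 0.15. Root markers moved in the same libraries: 9 of 17 rose and 1 fell, with 10 and 1 over the list alone and a median of 0.51 (camera adjusted p = 0.0121; adjusted p = 0.544 with an estimated correlation), a call lost with equal library totals (adjusted p = 0.0662). LRX1 rose by 1.69 ± 0.11, NRT2.1 by 1.54 ± 0.16 and COBL9, a root hair gene, by 1.42 ± 0.19, with adjusted p between 2.15e-07 and 7.15e-05.

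Of 14 flavonoid and anthocyanin genes 12 rose and 1 fell in the libraries labelled rlt1/2, as over the list alone, with a median of 1.09 (camera adjusted p = 0.000485; adjusted p = 0.596 with an estimated correlation), DFR rising by 1.73 ± 0.18. Of 17 jasmonate genes 11 rose and 2 fell, with 11 and 3 over the list alone and a median of 1.06 (camera adjusted p = 0.00568; adjusted p = 0.623 with an estimated correlation), a call lost with equal library totals (adjusted p = 0.053). CORI3 rose by 2.24 ± 0.18 and JAZ1 by 1.52 ± 0.14. Of 12 phosphate starvation genes 8 rose and 0 fell, as over the list alone, with a median of 0.49 (camera adjusted p = 0.0229; adjusted p = 0.544 with an estimated correlation). PPSPASE1 rose by 1.27 ± 0.12. Of 19 cold and drought genes 12 fell and 1 rose, with 12 and 2 over the list alone and a median of -1.05 (camera adjusted p = 0.000369; adjusted p = 0.544 with an estimated correlation). KIN2 fell by 2.34 ± 0.11 and RAB18 by 1.97 ± 0.12. Of 17 iron deficiency genes 10 fell and 3 rose, as over the list alone, with a median of -0.85 (camera adjusted p = 0.0273; adjusted p = 0.623 with an estimated correlation), a call lost without WT replicate 1 (adjusted p = 0.0685) or replicate 2 of the mutant (adjusted p = 0.107) and with DESeq2 (adjusted p = 0.0514). IMA3 fell by 2.31 ± 0.21 and F6'H1 rose by 1.80 ± 0.10. Of 19 auxin genes 12 fell and 5 rose, as over the list alone, with a median of -0.93 (camera adjusted p = 0.0313; adjusted p = 0.544 with an estimated correlation), a call lost without replicate 1 of the mutant (adjusted p = 0.0603), with edgeR (adjusted p = 0.0522), DESeq2 (adjusted p = 0.124) and a filter at 50 (adjusted p = 0.0552). SAUR20 fell by 1.76 ± 0.14 and YUC9, an auxin synthesis gene, rose by 2.72 ± 0.23.

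Groups that did not pass camera in the libraries labelled rlt1/2 were the clock (4 of 18 rose and 9 fell, as over the list alone; adjusted p = 0.107, with 0.0294 by DESeq2 and 0.0333 with equal library totals), salicylic acid defence (6 of 18 rose and 2 fell, as over the list alone; adjusted p = 0.146, and 0.0219 without replicate 2 of the mutant), heat shock (4 of 10 rose and 0 fell, with 3 higher over the list alone; adjusted p = 0.145, and 0.0457 with a filter at 50) and glucosinolate synthesis (6 of 20 rose and 3 fell, with 7 and 3 over the list alone; adjusted p = 0.371). PRR7 fell by 0.99 ± 0.08, SAG13, a senescence and defence marker, rose by 3.22 (2.62 without replicate 1 and 3.81 without replicate 2 of the mutant; call lost with robust fitting, adjusted p = 0.0549), HSP18.2 rose by 2.00 ± 0.19 and MYB29 fell by 0.99 ± 0.12. Of 11 other chromatin remodellers 4 fell and 0 rose, as over the list alone (camera adjusted p = 0.276), CHR12 falling by 0.58 ± 0.08. Of 9 ISWI subunits 3 rose and 2 fell, with 4 and 2 over the list alone; their median of 0.18 and the direction of camera (adjusted p = 0.717) were positive and their mean of -0.39 negative, RLT2 having the lowest value. CHR17 rose by 0.56 ± 0.07 and ARID5 by 0.33 ± 0.08. By size, BAM5 rose 79.0-fold from 229 and 292 to 12530 and 27700, RNS1, a ribonuclease, 42.0-fold, and DXPS1 at least 191-fold from no reads in WT; MAPKKK6 fell 11.5-fold. limma called 9926 of 20741 genes, 47.9%, with 4944 higher and 4982 lower; 1288 and 790 changed more than 2-fold, and edgeR called 9873, 9777 of them called by both. Equal library totals moved the median of all genes from 0.009 to 0.268 and gave 9663 higher and 2699 lower.

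**Figure D3:**
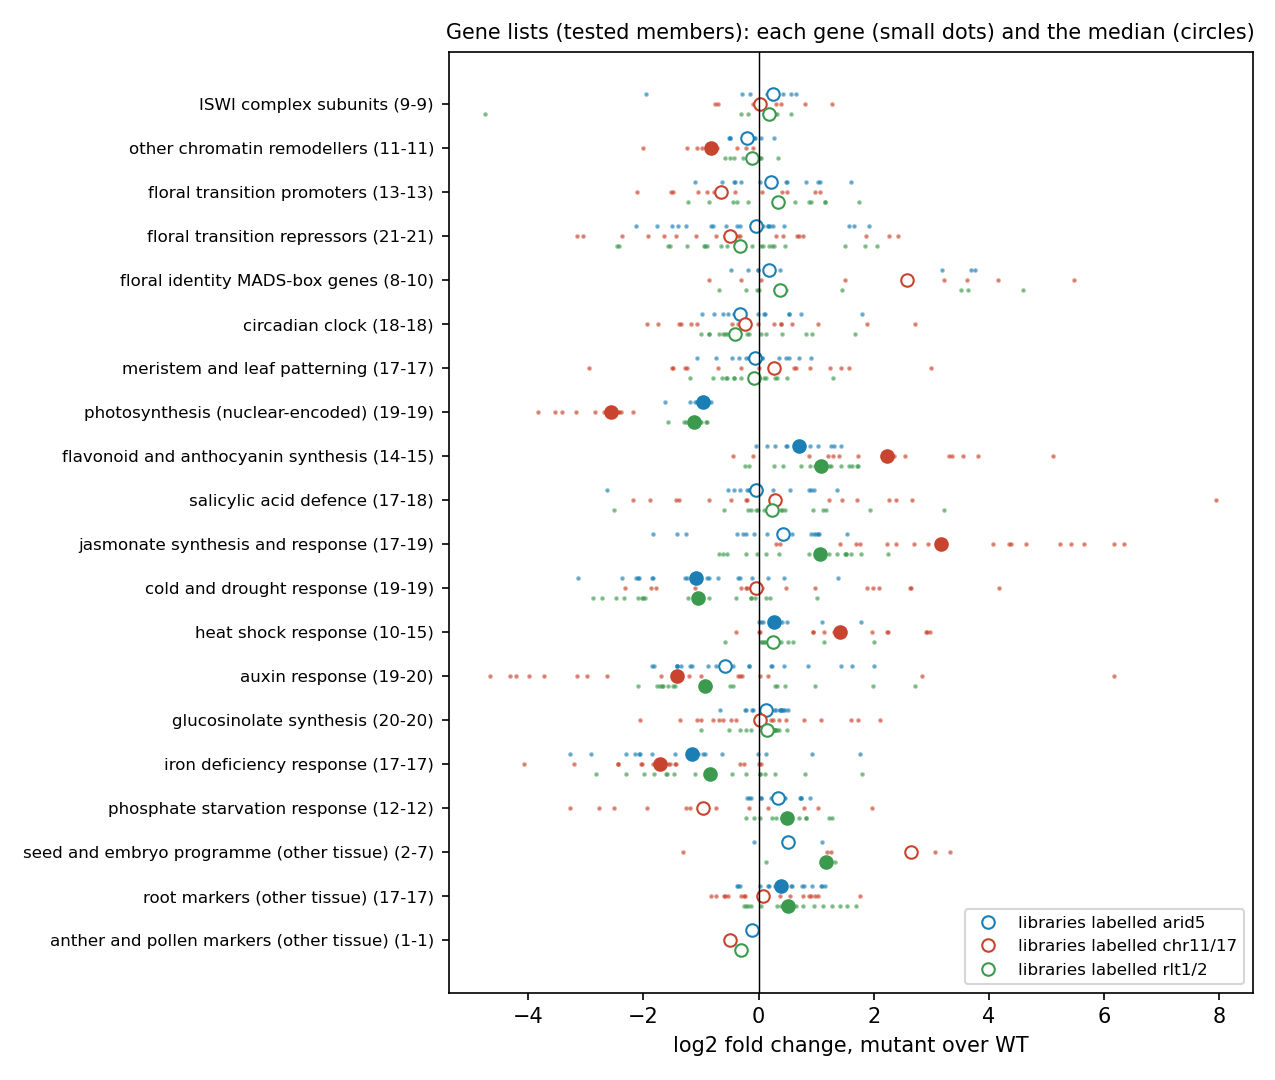
Log2 fold changes over WT (horizontal axis) of the 20 gene lists in the 3 mutants; small dots are genes, circles medians, filled where the list passed camera at the preset correlation, and numbers in brackets the fewest and most members tested. The median of the photosynthesis list lies at -0.97, -2.56 and -1.12 in arid5 and the libraries labelled chr11/17 and rlt1/2.

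The mutants were then set side by side, to ask how far the transcripts changed in 1 mutant also change in the others. Genes called in the same direction in all 3 were led upward by AP3, BAM5, GPT2, TH8 and UKL5, a uridine kinase, and downward by ACD6, which acts in defence, PCR1, PORA, AT1G26620 and AT5G45310. UKL5 rose by 4.17, 4.20 and 4.19, PCR1 fell by 4.08, 4.07 and 4.17, and GPT2 rose by 3.71, 8.15 and 4.90 in arid5 and the libraries labelled chr11/17 and rlt1/2. The sizes for UKL5 and PCR1 are limited by the 10 added before taking logs, so near-equal values do not measure equal changes. Across alternatives PCR1 ranged from -7.56 to -2.40 and UKL5 from 2.65 to 6.02 in arid5. Of 20258 genes tested in every table, 3033 were called higher and 3648 lower in all 3 mutants, against 379.9 and 460.7 for independent lists and averages of 0 and 0.02 in the simulations with shared controls. Unchanged simulated groups have hardly any called genes, so these averages do not measure what shared controls add among changed genes. Scaling to equal totals gave 5914 and 2027. As a pair, arid5 and the libraries labelled rlt1/2 shared 3988 higher and 4368 lower genes, against 1105.5 and 1243.1 for independent lists, and 5 genes were called in opposite directions. The libraries labelled chr11/17 opposed arid5 in 788 genes and those labelled rlt1/2 in 598. Of the genes called in both, 99.9% had the same sign in arid5 and the libraries labelled rlt1/2, 90.3% in arid5 and those labelled chr11/17, and 92.7% in the latter pair of labels.

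Across these genes, which are not independent replicates, the log2 fold changes correlated at 0.94 between arid5 and the libraries labelled rlt1/2, 0.64 between arid5 and those labelled chr11/17, and 0.71 between those labelled chr11/17 and rlt1/2, where unchanged simulated groups gave 0.51, 0.51 and 0.50. The covariances were 0.329, 0.44 and 0.55, each against 0.014 in the simulations. Part of the excess in overlap and covariance may come from the shared WT libraries, which could not be split. The spread of the fold changes was 0.56 (SD across genes) in arid5, 0.63 in the libraries labelled rlt1/2 and 1.24 in those labelled chr11/17.

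**Figure D4:**
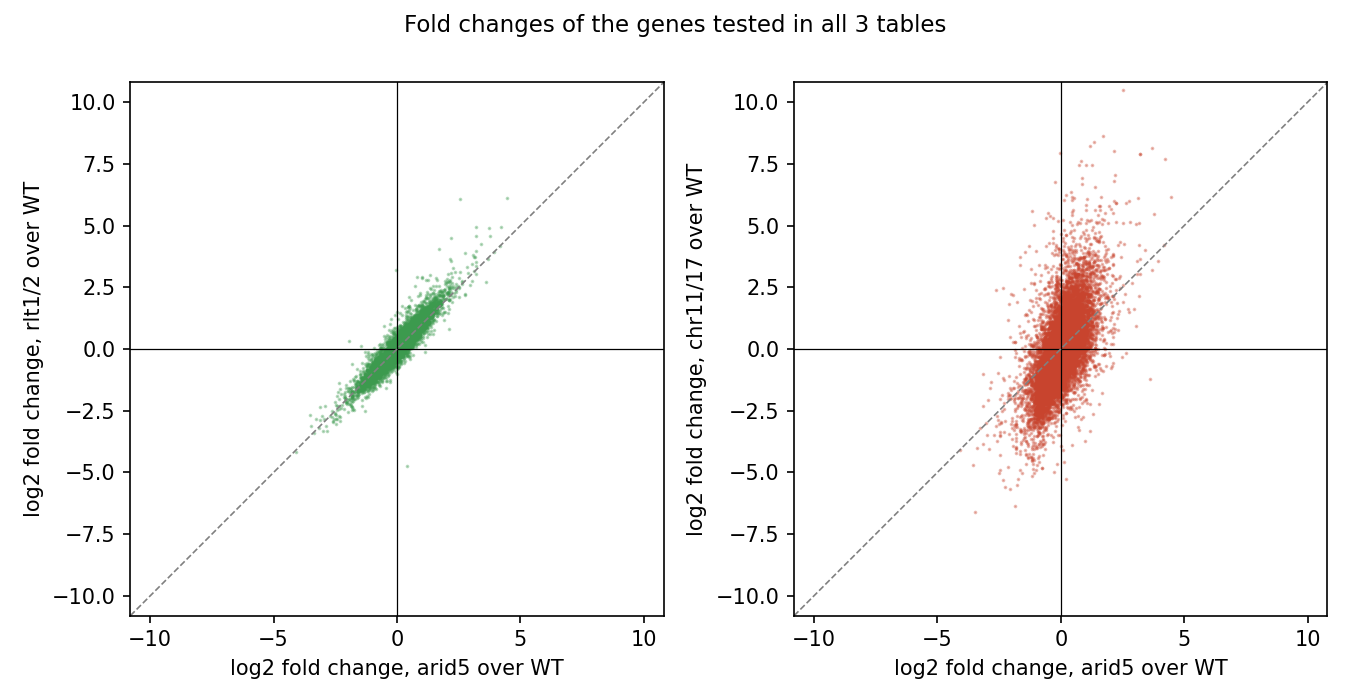
Log2 fold changes over WT of the 20258 genes tested in all 3 tables, arid5 on the horizontal axes, the libraries labelled rlt1/2 (left) and chr11/17 (right) on the vertical axes; points are genes and the dashed line marks equal values. Correlations are 0.94 and 0.64.

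Arid5 and the libraries labelled rlt1/2 were also tested directly against each other on recovered reads, and the genes that differed included ARID5 and RLT2. With edgeR's joint fit, RLT2 was lower by 5.34 (log2) and ARID5 higher by 2.32 in the libraries labelled rlt1/2, and SAG13 (3.39), DXPS1 (3.45), ELI3-2 (3.31), BAM5 (1.74) and LOX3 (1.09) were higher there. The fit called 78 of 21288 genes, 69 higher and 9 lower, with 1689 at an unadjusted p under 0.05. The count was 19 without arid5 replicate 2, 43 without arid5 replicate 1, 36 without replicate 2 of those labelled rlt1/2, 151 without either library labelled chr11/17, and 174 by DESeq2. Photosynthesis genes had 0 of 19 called between these mutants, with a median difference of -0.13. Jasmonate genes had 2 of 18 higher, or 14 over the list alone, with a median of 0.56, and salicylic acid defence genes 1 of 18, or 4 over the list alone. These differences had no set test. A gene not called here is not shown to be equal.

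The libraries labelled chr11/17 differed from both other mutants in most genes. All 19 photosynthesis genes were lower than in arid5, with a median difference of -1.54, and all 18 jasmonate genes were higher, with a median of 3.42. SVP was lower by 2.13 (edgeR adjusted p = 2.12e-05) and FT by 1.48 (edgeR adjusted p = 0.00428) than in arid5, and GH3.3 higher by 4.61 (edgeR adjusted p = 3.3e-09). Of 19 cold and drought genes 14 were higher and 0 lower than in arid5, with a median of 1.22, and of 11 other chromatin remodellers 9 were lower and 0 higher. In all, 13883 of 21288 genes differed between the libraries labelled chr11/17 and arid5, 6862 higher and 7021 lower, and 13800 between those labelled chr11/17 and rlt1/2, 6853 higher and 6947 lower.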

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

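The difference tests in this part were planned; the choice of genes called in opposite directions in 2 mutants was made after the values were seen. Among the named genes other than the mutated ones, 14 were called in opposite directions by limma in the libraries labelled chr11/17 and in another mutant, and 13 of them opposed both arid5 and the libraries labelled rlt1/2. They were chosen on the same libraries and for passing edgeR's joint fit too (adjusted p between 2.49e-09 and 0.000243), so that fit is no separate evidence. Values below are log2 differences of the libraries labelled chr11/17 from arid5, then from those labelled rlt1/2. No explanation was tested for them.

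Higher in the libraries labelled chr11/17 and lower in the others were the cold and drought genes COR15A (2.64 and 2.54) and RD29A (3.75 and 3.91), and RD20 opposed arid5 only (5.52). The jasmonate-responsive storage protein gene VSP2 differed by 2.89 and 2.02, the clock gene PRR9 by 1.85 and 1.95, and MYB34, a regulator of indole glucosinolates, by 0.75 and 1.04. PR1, a defence gene, differed by 5.32 and 5.14; its WT libraries stood far apart, at 821 and 82 normalised counts in the arid5 table, and without WT replicate 1 its fall in arid5 was 1.05 instead of 2.63, and 4.21 without WT replicate 2. Its call in arid5 was lost without a trend (adjusted p = 0.128) and with robust fitting (adjusted p = 0.312).

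Lower in the libraries labelled chr11/17 and higher in the others were the phosphate starvation genes IPS1 (-6.47 and -6.76), MGD3 (-5.22 and -5.31) and MGD2 (-2.09 and -1.90), which encode a noncoding RNA and enzymes of galactolipid synthesis. In limma IPS1 changed by -2.78 in the libraries labelled chr11/17, 0.89 in arid5 and 1.22 in those labelled rlt1/2. MGD3 changed by -3.27, 0.72 and 0.83 in the same order. The sizes for IPS1 and MGD3 thus depend on the scale and were given no interval. The nitrate transporter gene NRT2.1 differed by -2.10 and -2.51, the flowering gene AGL42 by -2.36 and -2.49, the glucosinolate pathway transporter gene BAT5 by -1.37 and -1.22, and AT1G29600 by -5.86 and -4.92. The rise of AGL42 in arid5 was 0.64 without WT replicate 1, against 1.02 with it.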

How the results depend on the processing

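Tests with equal library totals, camera with a trend and the overlap without the libraries labelled chr11/17 were chosen after the data were seen. Over 307 named-gene results and 4785 alternatives, 57 calls were lost with the same sign, 1 was lost with a change of sign and 7 were gained, and 283 results never changed. The change of sign was INO80 in the libraries labelled rlt1/2, at 0.004 (adjusted p = 0.972) with equal totals, where every gene shifts upward. Most named genes were picked for large changes or small adjusted p in these same libraries, which favours stable calls. Over all genes of arid5, 7464 of the 9846 calls were also made with equal totals and 7598 by limma without trend. Over 56 list results and 947 alternatives 53 calls were lost, 36 gained and 0 reversed; 15 more list and 16 named-gene alternatives changed sign without a call on either side. With an estimated correlation 0 lists passed in arid5, 0 in the libraries labelled chr11/17 and 0 in those labelled rlt1/2, against 6, 7 and 9, the adjusted p of the 22 lost calls lying between 0.544 and 0.623; fry, which does not compare with other genes, passed 8, 14 and 13. Camera with an estimated correlation rests on the 2 residual degrees of freedom, so few lists could pass. Heat shock genes in the libraries labelled chr11/17 had an estimated correlation of 0.001, under the preset 0.01. Their camera p, before adjustment, still went from 0.000537 to 0.067. For a list with an estimate near or under the preset, a loss is thus not by itself evidence against it. Photosynthesis genes had correlations of 0.935, 0.992 and 0.974 in arid5 and the libraries labelled chr11/17 and rlt1/2, far above the preset. If these estimates hold, the camera p-values of that list at the preset correlation are too small. Limma without trend was not run for lists, since camera had no trend.

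A fold threshold of 2 left 1497, 6883 and 2078 genes in arid5 and the libraries labelled chr11/17 and rlt1/2, and 529 higher and 412 lower genes in all 3. Without that threshold, equal totals gave 5914 higher and 2027 lower genes in all 3, against 3033 and 3648, and RLT1 in the libraries labelled rlt1/2 0.374. DESeq2 called 7135, 13096 and 7640 genes. Between the libraries labelled rlt1/2 and arid5, fitting only the libraries of these 2 mutants called 121 genes and DESeq2 174, with 19 to 151 when libraries were left out. Leaving out each library gave 7731 to 8925, 12420 to 14521 and 7692 to 10079 genes per mutant, and RLT1 from -0.04 to 0.239. Without the libraries labelled chr11/17 the overlap was 4037 higher and 4368 lower genes. Apart from fewer libraries or a stricter threshold, the cause was not tested.

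The replicate numbers share no stated batch. Deviations of same-numbered libraries correlated at -0.01, 0.01 and 0.176 between WT and arid5 and those labelled chr11/17 and rlt1/2, and at 0.158, -0.161 and -0.074 between arid5 and chr11/17, arid5 and rlt1/2, and chr11/17 and rlt1/2 labels, so the numbers are not shown to pair the samples. With the replicate block 9915, 14833 and 11364 genes were called. The block also moved 4 calls among lists and named genes: floral identity (adjusted p = 0.0408) and seed genes (0.0421) passed in the libraries labelled chr11/17, and in those labelled rlt1/2 CHR11 was called (0.02) and seed genes were not (0.0516). Depth limits FLC, FT and the seed genes, with few reads per library.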

Other observations

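The gene families in the first 2 paragraphs were chosen after the data were seen, as were the tests of explanations that follow them. Gene names in the reference that share a stem gave 145 families with at least 10 tested genes and 420 tests; 51 passed camera, 0 with an estimated correlation (lowest adjusted p = 0.816), and 10 families passed in all 3 mutants. Succinate dehydrogenase (SDH) genes, of the mitochondrial respiratory chain, rose throughout: 12 of 12 in arid5 (median 0.46), 13 of 13 in the libraries labelled chr11/17 (1.18) and 12 of 12 in those labelled rlt1/2 (0.55), each with camera adjusted p = 0.00103 (adjusted p = 0.816 with an estimated correlation). SDH1-2 rose by 1.41 and SDH3-1 by 0.63 in arid5. Genes named for the plastid transcriptionally active chromosome (PTAC) fell, 13 of 13 in arid5 (median -0.77, camera adjusted p = 9.63e-05), 12 of 13 in the libraries labelled chr11/17 (-1.51, 0.00177) and 13 of 13 in those labelled rlt1/2 (-0.76, 0.000222), each with adjusted p = 0.816 with an estimated correlation. The fall of the PTAC genes held with equal library totals. Those totals shift all genes upward, so they do not test the rise of the SDH genes.

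WRKY transcription factor genes rose more than they fell, 22 against 6 of 56 in arid5, 36 against 8 of 56 in the libraries labelled chr11/17 and 34 against 5 of 58 in those labelled rlt1/2, with camera adjusted p = 0.0142, 0.00155 and 0.00056 (adjusted p = 0.816 in each with an estimated correlation). Genes named for microRNA precursors (MIR) went the other way. They had 12 lower and 1 higher of 27, 15 lower and 3 higher of 24, and 12 lower and 0 higher of 31. Their camera adjusted p was 0.00257, 0.0432 and 0.000222 (adjusted p = 0.816 in each with an estimated correlation). Totals per gene hold no position and use of strand is not given, so reads of overlapping transcripts cannot be told apart from precursors.

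Photosynthesis transcripts fell in all 3 mutants, and a wrong factor per library is argued against by medians of -0.70 in arid5, -2.40 in the libraries labelled chr11/17 and -0.84 in those labelled rlt1/2 with equal library totals. A lower share of green tissue would raise root markers together and cannot be told apart from the genotype in any of the mutants. In the libraries labelled chr11/17 7 root markers rose and 3 fell (variance ratio 23.0), with no rise as a list (camera adjusted p = 0.717). With 71.8% of genes called there, changes of single root genes can hide a shared rise. In arid5 and those labelled rlt1/2 9 of 17 rose and 1 fell in each. The list passed camera upward in both (adjusted p = 0.0112 and 0.0121, and 0.544 in each with an estimated correlation). The markers varied there too (variance ratios 14.9 and 22.1). A difference between libraries that depends on the level of the gene is argued against as the whole cause in the libraries labelled chr11/17. There the median rank went from 11 to 84 and the median was -1.73 after quantile normalization. In arid5 (median 0) and those labelled rlt1/2 (-0.03) such a difference cannot be told apart from the genotype. The listed genes keep their ranks in both, which fixes those medians. Of 94 other genes at the same WT level 76, 75 and 73 also fell in arid5 and the libraries labelled chr11/17 and rlt1/2. Their medians were -0.81, -2.02 and -0.92 in the same order. They were chosen by level and may include photosynthesis genes outside the list, so their fall decides nothing between level and genotype. Harvest at another time of day may contribute and cannot be told apart from the genotype: harvest times are not in the labels, and of the dawn genes CCA1 fell and LHY rose in each mutant, LHY exceeding CCA1 by 0.83, 1.65 and 1. A direct or developmental effect of the mutations stays open and was not tested.

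CHR11 was higher in the libraries labelled chr11/17. A swap with another mutant of the series is argued against by ARID5 at 0.30 and RLT2 at -0.10 there, since each is far lower in its own mutant. Reads of CHR17 counted for CHR11 would leave the sum of both unchanged, but the sum was 1.86 times that in WT. Transcript outside the mutated part of the genes may remain, with CHR17 at -0.75; totals per gene hold no position, so this cannot be told apart from other plants than the label says. A biological rise of a mutated transcript was not tested.

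Fold changes in arid5 and in the libraries labelled rlt1/2 were alike. Shared WT libraries that differ only by the spread between replicates gave a simulated covariance of 0.014, against 0.329 observed. A deviation common to both WT libraries would enter every fold change. It was not simulated and cannot be told apart from the genotypes. The same plants under both labels are argued against by ARID5, higher by 2.32, and RLT2, lower at -5.34, in the libraries labelled rlt1/2. Loss of a common complex, and growth or harvest together, stay open and were not tested, and the labels name no batch.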
